A study of Manihot esculenta with 9 samples.

How the data were processed

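Messenger RNA of cassava leaves was measured by stranded poly(A) RNA sequencing in 9 libraries, 3 of each line, and all 9 were used. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with HISAT2, and quantified with StringTie, and DESeq2 was used for expression differences; versions and settings of these tools are not given in the sources used here. Read counts per gene were deposited by the authors as whole numbers for 34307 genes, without normalization. FPKM values were deposited by the authors beside them, and in a check on 57 chloroplast genes the length implied by count, library total and FPKM was 1.28 to 1.31 times the length in the gene table in every library. TPM values were deposited by the authors as well, scaled to a constant total per library. Fits on them used no further factors for library composition, so a call lost on the TPM scale may reflect this scaling. How reads that match several genes were counted is not given in the sources used here, so near-identical copies and overlapping genes are uncertain. The labels name an older assembly than the reference table of gene names, which is M.esculenta_v8. All 34307 gene identifiers matched that table, so it was used for names, product descriptions, chromosome and gene order, and no coordinates are given.

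Differences between lines were computed from the deposited counts. Of the 34307 genes 28086 had a count, and 22808 were tested after edgeR's filterByExpr with the lines as groups (21469 protein-coding, 18168 with a product description). TMM factors ran from 0.753 in HB100 replicate 1 to 1.17 in TMS-IBA 980581 replicate 1. One mean per line was fitted to all 9 libraries with edgeR's robust quasi-likelihood model, and the contrasts were TMS-IBA 980581 minus HB100, MKUC64-36-160 minus HB100, MKUC64-36-160 minus TMS-IBA 980581, and the mean of the resistant lines minus HB100. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard errors (SE) and CPM as mean ± SD of 3 libraries on TMM-scaled totals. Where a line had no read for a gene, the fold is a lower bound against 3 counts over the 3 libraries of that line. With 1 to 3 counts the ratio of counts is given with its exact 95% interval. These intervals do not use the spread between libraries.

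From product descriptions 38 gene lists were fixed, covering immune receptors, RNA silencing and DNA methylation, hormone pathways, pathogenesis-related and stress proteins, photosynthesis, ribosomes, primary and secondary metabolism, and cell types of the leaf. Of these, 37 had the minimum of 5 tested members. They were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Some descriptions are broad: the cyanogenic list also holds glucan endo-1,3-beta-glucosidases, and the chlorophyll list holds translocon components. Shares of called genes per chromosome were compared with the other chromosomes by Fisher's exact test. The named genes are those that a rule picked: per comparison, the 5 largest rises and 5 largest falls among called, annotated genes of at least 5 CPM without overlap between libraries; the 3 members of smallest adjusted p in each list past the threshold; the 10 largest shared rises and 10 largest shared falls; the 2 members of smallest adjusted p called in both resistant lines in each of 6 defence lists; and a gene fixed by name. The rule gave 83 genes. The lines' groups, contrasts, gene lists, this rule and most alternatives were fixed before the data were examined. The Fisher's exact test of called shares per list, adjusted over the 37 lists, was added after seeing the data, as were the rRNA covariate, the fits without organelle genes or without the libraries of highest rRNA share, and the permutations of neighbouring genes. POLD1 was matched by its product description, and a pair of cap-binding protein genes fixed with it could not be matched to the table and are not reported.

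Alternatives were median-of-ratios factors, DESeq2, limma-voom, limma on log2 of TPM + 1 and of TPM + 0.1, no low-count filter, a filter of 5 CPM in 3 libraries, only the libraries of the lines compared, blocks by replicate number, a log2 fold change of at least 1, a test against a fold of 1.5, a model of resistance classes, and leaving out each library in turn. Replicate numbers were checked for pairing: libraries with the same number in the description correlated at -0.109 to 0.321 in their deviations from the line means (mean 0.091, 9 pairs), with the same number in the title at -0.14 to 0.272 (mean 0.016, 6 pairs), and with neither at -0.252 to 0.228 (mean -0.06, 15 pairs). The description numbers of HB100 and MKUC64-36-160 correlated at 0.198, 0.24 and 0.168, each over the 0.1 taken as pairing, but for the other pairs of lines not every value was. As fixed beforehand, the fit of all lines had no block, and blocks were run as alternatives. Shared controls were simulated with 20 draws of unchanged groups. The HB100 libraries were drawn too, from the mean of each gene over all 9 libraries. The fit was tested on data drawn from the same means and the sizes of the 9 libraries, with 200 of the 22808 genes changed in TMS-IBA 980581. Against HB100, 34% of genes changed 2-fold and 84% of genes changed 4-fold were called, all with the right sign. There 5 unchanged genes were called. In simulated data for MKUC64-36-160 against HB100, 2 of 200 unchanged lists had a camera p under 0.05. Genes were drawn independently there, so this does not show how camera treats lists of correlated genes. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.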

Results

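Leaf RNA of cassava (Manihot esculenta) was sequenced in 9 libraries, 3 biological replicates for each of 3 lines. HB100, short for Huay Bong 100, is the line labelled as not resistant to CMV, and TMS-IBA 980581 and MKUC64-36-160 are the lines labelled as resistant. The leaves were 6 months old and every library carries the same CMV treatment label, so no untreated leaf was compared. With 1 non-resistant line, resistance class and line are the same contrast. Total counts were 23038182, 20898862 and 20724205 in HB100, 26659458, 25936317 and 26196305 in TMS-IBA 980581, and 24995783, 26797071 and 19667868 in MKUC64-36-160. Ribosomal RNA genes took 25.2 ± 4.85% of the counts in HB100 (SD, n = 3), 16.6 ± 1.82% in TMS-IBA 980581 and 20.5 ± 7.25% in MKUC64-36-160. The highest shares were 30.8% in HB100 replicate 1 and 28.4% in MKUC64-36-160 replicate 3, with 28.1% and 26.5% of counts from chloroplast rRNA. Between 24491 and 25538 genes had a count in a library. A library with no count for a gene allows up to 3 counts, 0.11 to 0.15 CPM (counts scaled to library size) at these depths, and this floor and the intervals given with ratios cover counting error only.

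The lines separated in the leading components of log2 CPM. HB100 libraries lay at -95.1 to -71.7 on the component holding 39.7% of the variance, and the resistant lines at 31.3 to 52.1. The next component, with 22.2%, placed TMS-IBA 980581 at 45.7 to 61.4 and MKUC64-36-160 at -70.8 to -38.7.

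**Figure D1:**
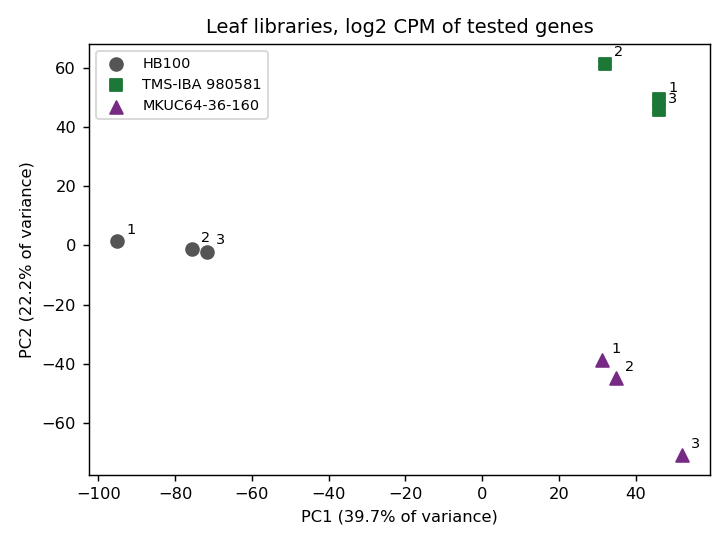
Scores of the 9 libraries on the leading principal components of log2 CPM, with the percent of variance on each axis and 1 point per library. HB100 libraries sit at the left, TMS-IBA 980581 at the upper right and MKUC64-36-160 at the lower right.

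Which leaf transcripts set TMS-IBA 980581 apart from the non-resistant line was asked first. The largest rises were of genes without a read in HB100. A gene missing from a line, or an allele too diverged to align, would also leave no reads. For genes without a read in a line, here and below, this was not told apart from a lack of expression. A BURP domain-containing protein 3-like gene on chromosome 16 (LOC110604203) stood at 40.5 ± 4.05 CPM (SD, n = 3) in TMS-IBA 980581, at least 829-fold higher, although limma-voom gave it an adjusted p of 0.073. An ankyrin repeat gene of the BDA1 type (LOC110624321, 15.6 ± 1.39 CPM) was at least 319-fold higher, the chloroplast peptidyl-prolyl isomerase gene CYP26-2 (LOC110614907, 14.5 ± 0.0905 CPM) at least 296-fold, and a syntaxin-51-like gene (LOC122722368, 14 ± 1.18 CPM) at least 286-fold. The cytochrome P450 71AU50 gene LOC110627654 had reads in TMS-IBA 980581 alone of the 3 lines, at 9.02 ± 2 CPM, and was at least 183-fold higher than in HB100.

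Other transcripts of HB100 had no read in TMS-IBA 980581. A probable amidase gene on chromosome 4 (LOC110612932) stood at 71.1 ± 0.686 CPM in HB100 and was at least 2060-fold lower in TMS-IBA 980581. The signal peptide peptidase-like 2 gene LOC110616843 was at least 859-fold lower, and a cytochrome P450 CYP736A12-like gene (LOC122723240, 15.3 ± 1.35 CPM in HB100) at least 440-fold. The receptor kinase genes PERK15 (LOC110608280) and PERK14 (LOC110607770), both on chromosome 9, were at least 679-fold and 521-fold lower. How reads matching several copies were counted is not given, so levels of single PERK, BDA1 and 28S rRNA copies are uncertain. Adjusted p of these 10 genes lay between 2.2e-06 and 0.0027 in edgeR's quasi-likelihood test.

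In all, 2564 of 22808 tested genes (11.2%) differed, 1260 higher and 1304 lower in TMS-IBA 980581, and 1647 of them by a log2 fold change of at least 1. The libraries of the lines did not overlap in 2557 of the called genes and in 34.6% of all tested genes, where chance gives 10% for 3 against 3. An unadjusted p under 0.05 was reached by 6117 genes. On the TPM scale (log2 of TPM + 1) the median of all genes moved from -0.01 to 0.17 and the share of called genes that were higher from 49.1% to 65.9%. The count fell to 1414, 1540 and 1467 without replicates 1, 2 and 3 of TMS-IBA 980581, to 1642 without HB100 replicate 2, and to 1435 with the rRNA share as a covariate.

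Chloroplast-encoded transcripts were the 1 list of 37 that passed camera with its preset correlation in this comparison; fry's test of 1 direction gave them an adjusted p of 0.37 and passed flower organs and senescence instead (0.035 each). Their median log2 fold change was -0.97, with 1 of 58 members above 0 (camera adjusted p = 1.6e-06, but adjusted p = 0.99 with an estimated correlation). Single members showed little: rpoC2, a subunit of the plastid RNA polymerase, fell by 1.63 ± 0.43 on the log2 scale (SE; adjusted p = 0.041), from 177 ± 123 to 57.3 ± 7.58 CPM, and the other 57 were not called. The next members, rpoC1 at -1.45 and clpP at -1.09, had adjusted p of 0.05 and 0.051, and the rpoC2 call ended without HB100 replicate 1 (adjusted p = 0.057), without any of 5 other libraries, and with limma-voom (adjusted p = 0.052). Adjusted over the list alone, edgeR called 0 members, 29 were lower at an unadjusted p under 0.05, and DESeq2 called 20. The level of these transcripts moved with the rRNA share of the library. Without HB100 replicate 1 the median was -0.37 (camera adjusted p = 0.056), and with the rRNA share as a covariate it was 0.03 (adjusted p = 0.84). As that share was mostly chloroplast rRNA (28.1 of 30.8% in HB100 replicate 1), the covariate would also take out a chloroplast difference of another cause.

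**Figure D2:**
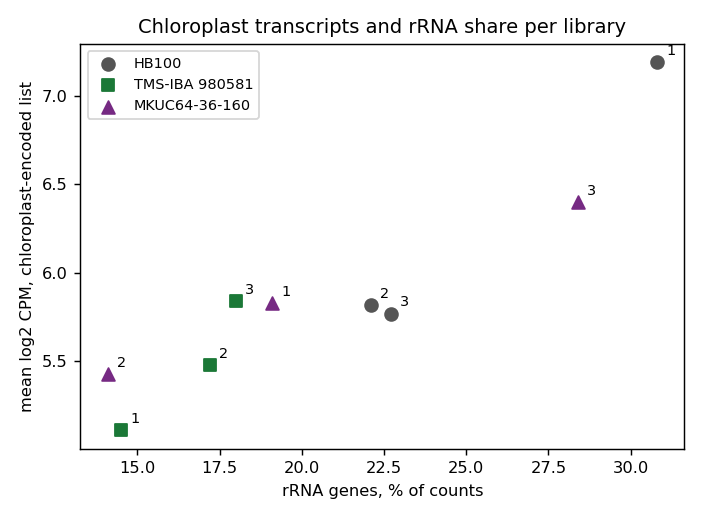
Mean log2 CPM of the chloroplast-encoded list against the rRNA share of counts in percent, 1 point per library and 1 colour per line. The level rises with the rRNA share, and HB100 replicate 1, at 30.8% rRNA and 7.19 log2 CPM, lies highest.

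NLR receptor genes, which encode intracellular immune receptors, were called more often than other genes, in both directions. Of 177 measured members 31 rose, 18 fell and 128 were not called, and adjusted over the list alone 42 rose and 30 fell. The called share was 27.7%, against 11.1% of the other genes (Fisher's exact test, two-sided, adjusted p = 7.2e-08). This test takes genes as independent, while neighbours of the same product name were often called together (63 pairs, against 1 to 10 permuted). The exact p-values of this and all other list shares may therefore be too small. Receptor-like kinases and proteins followed, with 50 of 656 higher and 68 lower (71 and 82 adjusted over the list alone), a share of 18% against 11% (exact adjusted p = 4.1e-06). Starch and sucrose genes also stood out, with 8 of 68 higher and 11 lower, 27.9% against 11.2% (exact adjusted p = 0.0012). None of these 3 lists passed camera (adjusted p = 0.57, 0.57 and 0.98). Photosystem and light-harvesting genes had 0 of 80 members called by edgeR, with 9 lower at an unadjusted p under 0.05 and 6 called by DESeq2. That share of 0% against 11.3% was lower than in other genes (exact adjusted p = 0.0012), as were those of cytosolic ribosomal proteins (4.69%, 0.0023) and cell cycle genes (1.19%, 0.0051).

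**Figure D3:**
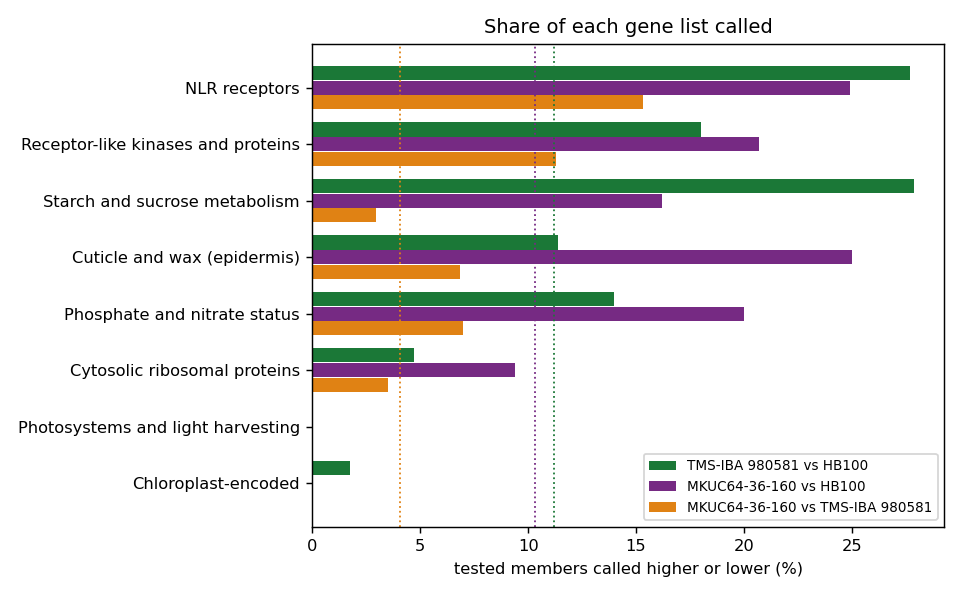
Percent of the tested members of 8 gene lists that were called, in either direction, in each comparison of lines. Dotted lines mark the share among all tested genes, 11.2%, 10.3% and 4.05%; NLR and receptor-like genes lie above it in all 3 comparisons.

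Which transcripts set MKUC64-36-160 apart from the non-resistant line was asked next. The BURP domain gene LOC110604203 (37.6 ± 32.1 CPM), the BDA1 gene LOC110624321 (17.2 ± 3.75 CPM) and CYP26-2 LOC110614907 (15.7 ± 2.75 CPM), without a read in HB100, were at least 642-fold, 365-fold and 311-fold higher here too, with limma-voom at an adjusted p of 0.097 for the first. The SKP1-like protein 1B gene LOC110609466, of the ubiquitin ligase family, stood at 27.6 ± 2.7 CPM in HB100 and had no read in MKUC64-36-160, at least 649-fold lower. Endochitinase 1 (LOC110612600), a chitin-degrading enzyme, stood at 15.1 ± 0.944 CPM in HB100 and was at least 353-fold lower in MKUC64-36-160, where it had no read, and the terpene synthase 3 gene LOC110603788 was lower by a ratio of 187 (95% counting interval 63.7 to 912). The cytochrome P450 genes LOC122723240 and LOC110620487 of the CYP736A12 type were at least 356-fold and 131-fold lower. A pair of further rises rested on uneven replicates: a GDSL esterase gene (LOC110603451, 13.9 ± 16.2 CPM, at least 223-fold, adjusted p = 0.042) lost its call without any 1 of 7 libraries and at an adjusted p of 0.26 with limma-voom, and eugenol synthase 1 (LOC110605447, 7.31 ± 7.28 CPM, at least 124-fold) with limma-voom at 0.1.

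Cytosolic ribosomal protein genes were higher in MKUC64-36-160 as a group, though replicate 1 lay within the range of HB100. Mean log2 CPM of the list was 4.87, 5.06 and 5.23 in HB100 replicates 1 to 3 and 4.94, 5.46 and 5.58 in those of MKUC64-36-160. Their median log2 fold change was 0.32, with 230 of 256 members above 0 (camera adjusted p = 1.8e-06, adjusted p = 1 with an estimated correlation). By gene, 18 rose and 6 fell (18 and 5 adjusted over the list alone). 60S ribosomal protein L4 (LOC110623241) went from 12.5 ± 3.21 to 82.1 ± 25.6 CPM, a log2 fold change of 2.72 ± 0.29 (adjusted p = 0.00059), L3-2 (LOC110624418) rose by 1.28 ± 0.19 and L23a (LOC110612811) by 1.2 ± 0.19. The group call ended when HB100 replicate 1 and MKUC64-36-160 replicate 3, the libraries of highest rRNA share, were both left out (adjusted p = 0.47).

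Receptor-like kinases and proteins were lower as a group, with a median of -0.25 (camera adjusted p = 0.016, but adjusted p = 1 with an estimated correlation). Of 656 members 38 rose and 98 fell (59 and 132 adjusted over the list alone), and the called share was 20.7% against 10% of other genes (exact adjusted p = 6.1e-14). The members that fell with the smallest adjusted p were RLP15 (LOC110608438, -5.17 ± 0.51), RLP1 (LOC122721772, -3.69 ± 0.34) and CRK10 (LOC110604445, -3.04 ± 0.29), with adjusted p of 0.00036, 0.00028 and 3e-04. NLR genes had 16 members higher and 28 lower (20 and 36 adjusted over the list alone), 24.9% against 10.2% (exact adjusted p = 5.2e-07). The receptor-like call as a group ended without HB100 replicate 2 (camera adjusted p = 0.089) or MKUC64-36-160 replicate 3 (0.14).

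Salicylic acid signalling, WRKY and abscisic acid genes were also lower as groups with the preset correlation of camera, but not with an estimated one (adjusted p = 1 for each). In the salicylic list 5 of 34 members fell and 0 rose (median -0.22, camera adjusted p = 0.043); they included both genes for PAD4, a lipase-like regulator of basal immunity, and CBP60A (LOC110630838, -0.76 ± 0.13, adjusted p = 0.0056, but 0.089 on the TPM scale). In the WRKY list 6 of 77 fell and 0 rose (median -0.22, adjusted p = 0.039; 3 adjusted over the list alone), among them WRKY48 (LOC110601688, -2.35 ± 0.36), WRKY20 (LOC122723343, -1.02 ± 0.16) and WRKY15 (LOC110627429, -1.39 ± 0.27). Of 50 genes of the abscisic acid and drought list 4 fell and 0 rose (median -0.23, adjusted p = 0.043; 8 adjusted over the list alone). ABA 8'-hydroxylase 3 (LOC110606357), which breaks down abscisic acid, fell by 2.15 ± 0.22, and the late embryogenesis genes LOC110626929 and LOC110609866 fell by 3.33 ± 0.47 and 1.98 ± 0.37. At an unadjusted p under 0.05, 1, 3 and 1 members of these lists were higher, and DESeq2 called 1, 1 and 0 of them. Leaving out 1 library ended the WRKY call without HB100 replicate 1 (0.063) or 2 (0.089) or MKUC64-36-160 replicate 3 (0.38), the abscisic acid call without HB100 replicate 1 (0.063) or 3 (0.13) or MKUC64-36-160 replicate 2 (0.097), and the salicylic call without any of 6 libraries (0.05 to 0.16).

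Chloroplast-encoded genes had a median of -0.46 in MKUC64-36-160 against HB100 (adjusted p = 0.042) with 0 of 58 members called by edgeR, 7 lower at an unadjusted p under 0.05 and 3 called by DESeq2; the members with the smallest adjusted p, ycf1 (-1.44 ± 0.48), rpoC2 (-1.22 ± 0.43) and rpoA (-1.26 ± 0.46), were at 0.095, 0.11 and 0.12. Photosystem genes likewise had 0 of 80 members called by edgeR (2 higher and 1 lower at an unadjusted p under 0.05, 1 by DESeq2), and both shares were lower than the 10.4% of other genes (exact adjusted p = 0.026 for chloroplast-encoded and 0.0037 for photosystem genes). Without HB100 replicate 1 the chloroplast median was 0.14 and the camera direction turned (adjusted p = 0.66), as it did with the rRNA covariate (0.44). The call also ended without MKUC64-36-160 replicate 1 (0.13) or 2 (0.44). Each of the 6 lists past the threshold in this comparison had an adjusted p of 1 with an estimated correlation, and fry's test of 1 direction called 0 of them, with 6 of 37 lists at an unadjusted p under 0.05.

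Of the 22808 genes, 2357 (10.3%) differed between MKUC64-36-160 and HB100, 1152 higher and 1205 lower, with 1538 at a log2 fold change of at least 1. An unadjusted p under 0.05 was reached by 5805 genes. Libraries of the lines did not overlap in 2353 of the calls and in 28.1% of all tested genes, against the 10% of chance. The count was 1448 without HB100 replicate 2, and 1398 without the libraries of highest rRNA share in HB100 and MKUC64-36-160.

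The resistant lines shared large differences from HB100, which the comparison of resistance classes asks for. Besides the BURP, BDA1 and CYP26-2 genes, a cell number regulator 2 gene on chromosome 1 (LOC110620072) went from 0.0908 ± 0.0786 CPM in HB100 to 54.3 ± 14.2 in TMS-IBA 980581 and 23.2 ± 5.48 in MKUC64-36-160, log2 fold changes of 9.05 ± 0.44 and 7.83 ± 0.44. The BDA1 genes LOC110625284 and LOC110624320 on chromosome 10 rose by 7.87 and 5.66 in the former and 7.78 and 5.71 in the latter, and the MADS-box gene LOC110608692 by 7.43 and 7.48. Fatty acyl-CoA reductase 3 (LOC110613265), of wax synthesis, had no read in HB100 and was at least 110-fold and 107-fold higher. The rise of ABP19a (LOC110610934) was less certain, with adjusted p of 0.035 and 0.013 in edgeR and 0.35 and 0.33 in limma-voom.

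Transcripts far lower in both resistant lines included a 28S rRNA gene on chromosome 18 (LOC122722573), at 3520 ± 282 CPM in HB100 and 18.2 ± 8.85 and 23.3 ± 8.54 CPM in TMS-IBA 980581 and MKUC64-36-160. SKP1-like LOC110609466 was lower in TMS-IBA 980581 by a ratio of 1200 (counting interval 332 to 9940). Terpene synthase 3 (LOC110603788) had no read there and was at least 231-fold lower. The zinc finger gene LOC122721768 was lower by ratios of 198 (67.3 to 964) in TMS-IBA 980581 and 160 (54.5 to 780) in MKUC64-36-160, and the nucleoplasmin-like gene LOC110623441 by 171 (58.1 to 833) in the former, while in the latter it fell by 6.29 on the log2 scale. A cytoplasmic malate dehydrogenase gene (LOC110629152) fell by 6.68 ± 0.65 and 6.17 ± 0.64, and the ABC transporter C genes LOC110610977 and LOC122723244 by 5.7 to 6.63 (log2).

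**Figure D4:**
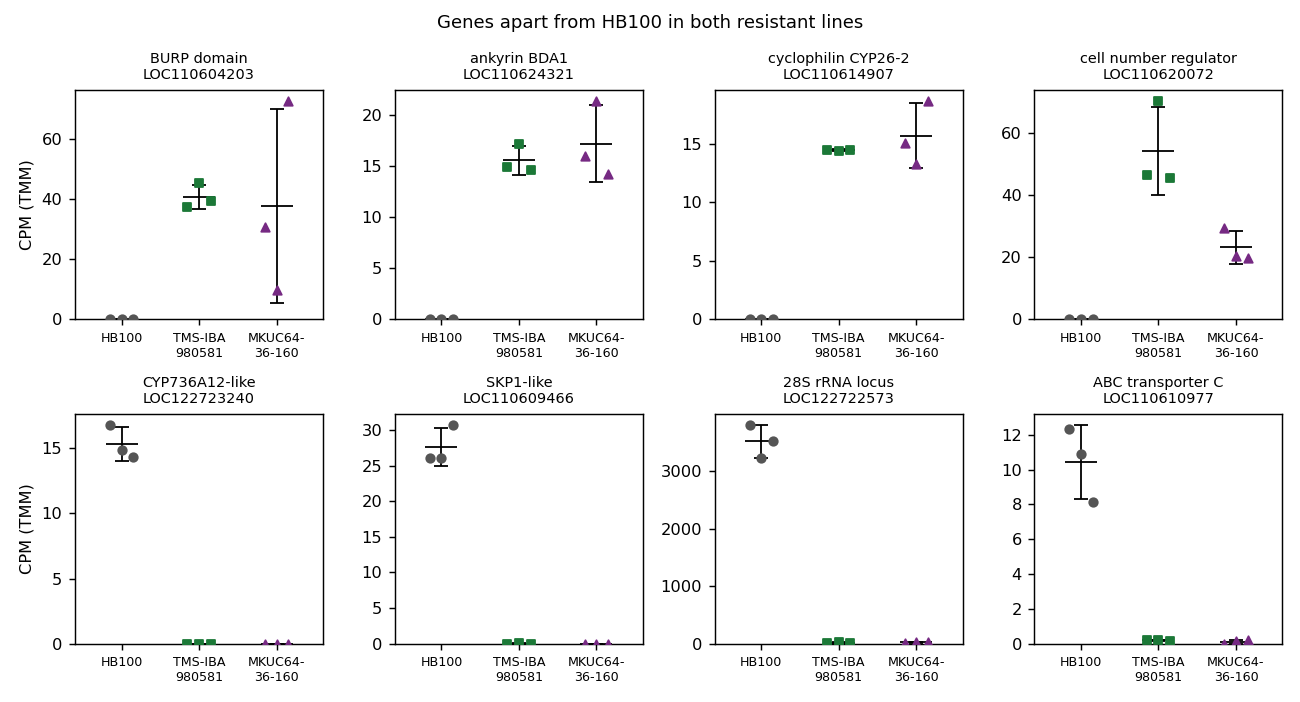
CPM of 8 genes that differed from HB100 in both resistant lines, 1 panel per gene; points are libraries, bars are means with SD (n = 3). The genes of the upper panels have little or no signal in HB100, and those of the lower panels little or none in the resistant lines.

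Among defence genes fixed as lists, 13 NLR genes rose in both resistant lines and 13 fell in both. The NLR gene LOC110622556 on chromosome 9 rose from 0.799 ± 0.339 CPM in HB100 to 41.5 ± 3.39 in TMS-IBA 980581 (52.4-fold) and 18 ± 1.48 in MKUC64-36-160 (22.7-fold), and LOC110626958 on chromosome 11 fell from 27.3 ± 5.24 to 3.61 ± 0.437 and 3.1 ± 0.486 CPM. PAD4 LOC110627739 fell from 47.7 ± 7.96 to 8.57 ± 0.963 and 22.1 ± 2.33 CPM and PAD4 LOC110628137 from 65.8 ± 12.8 to 6.44 ± 1.93 and 30.4 ± 0.895 CPM; in all 3 salicylic genes fell in both lines. AGO2 (LOC110618594), an Argonaute of antiviral RNA silencing, fell from 3.34 ± 0.743 to 0.723 ± 0.524 CPM (adjusted p = 0.015) and 0.211 ± 0.029 CPM (adjusted p = 0.002). The first of these calls ended without HB100 replicate 2 (0.052) or TMS-IBA 980581 replicate 1 or 3 (0.052 and 0.062). AGO5 (LOC110613720) fell by 0.48 ± 0.12 and 0.85 ± 0.13, the former without a call in any of 6 fits that left out 1 library of HB100 or TMS-IBA 980581 (0.051 to 0.12) and the latter without one on the TPM scale (0.065). A subunit of RNA polymerase V (LOC110618474), which acts in RNA-directed DNA methylation, rose from 10.8 ± 1.28 to 17.1 ± 1.56 and 20.8 ± 1.44 CPM.

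**Figure D5:**
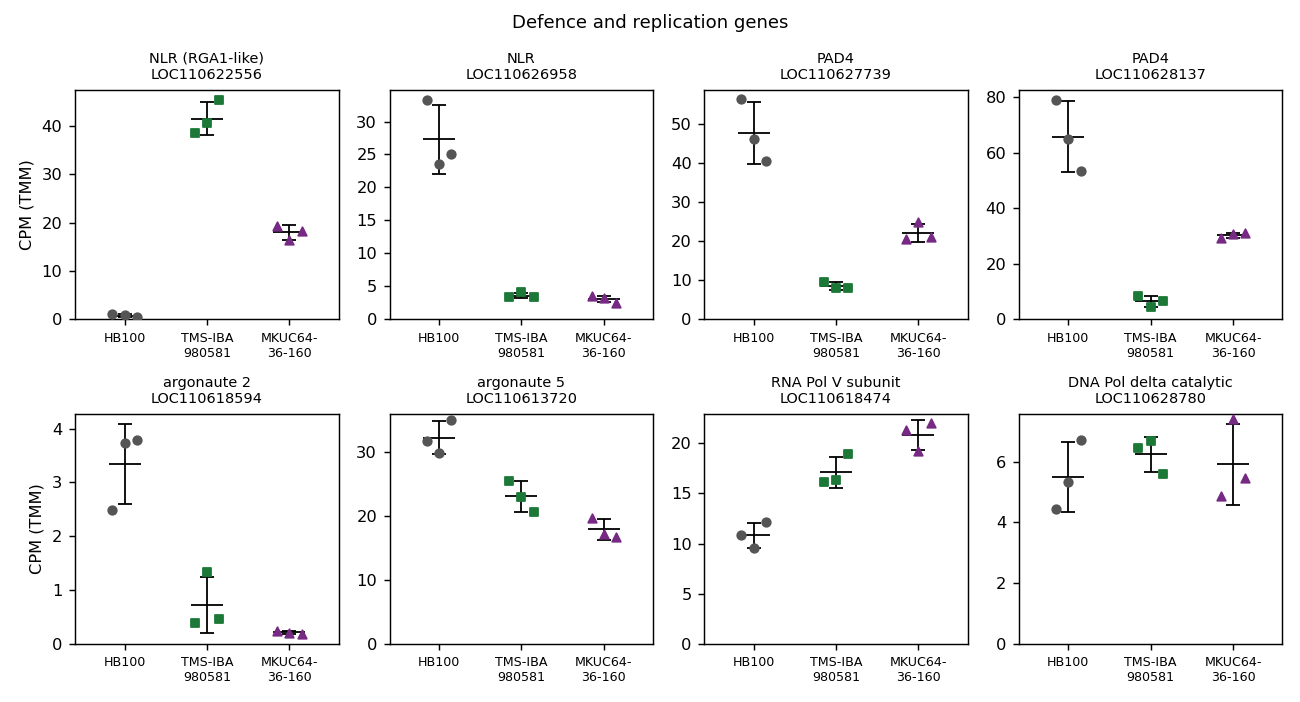
CPM of 8 defence, RNA silencing and replication genes in the 9 libraries, 1 panel per gene; points are libraries, bars are means with SD (n = 3). NLR LOC110622556 is higher and the PAD4 and Argonaute genes lower in the resistant lines, while POLD1 differs by less than the spread of its libraries.

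Of 88 pathogenesis-related genes 6.82% were called in TMS-IBA 980581 and 7.95% in MKUC64-36-160, and of 35 DNA replication genes 17.1% and 5.71%, against 11.2% and 10.3% of all tested genes (Fisher's exact adjusted p = 0.61 for both lists in the former and 0.95 in the latter). A beta-1,3-glucanase gene (LOC110609347) was the 1 pathogenesis-related gene to change in both lines, with rises of 3.37 ± 0.32 and 2.12 ± 0.32. In the DNA replication list the RPA32B gene LOC110617564 rose by 1.54 ± 0.18 and 1.11 ± 0.18, the second without a call on the TPM scale (adjusted p = 0.067), and a ribonucleotide reductase gene (LOC110610510) fell by 0.87 ± 0.18 and 0.79 ± 0.18, neither called on the TPM scale (adjusted p = 0.14 and 0.084). POLD1 (LOC110628780), the catalytic subunit of DNA polymerase delta and fixed for its reported link to cassava mosaic disease resistance, stood at 5.49 ± 1.15, 6.24 ± 0.572 and 5.92 ± 1.33 CPM in HB100, TMS-IBA 980581 and MKUC64-36-160. Its log2 fold changes of 0.18 ± 0.22 and 0.11 ± 0.22 were within the spread of the libraries (adjusted p = 0.64 and 0.8). Variants in its sequence were not analysed here, so its transcript level does not decide on that link.

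Both resistant lines differed from HB100 in the same direction in 1271 genes, 647 higher and 624 lower, which is 49.6% of the calls of TMS-IBA 980581 and 53.9% of those of MKUC64-36-160. Independent lists of these lengths would share 63.64 and 68.89. Unchanged groups simulated against a common simulated HB100 group shared 0.05 calls on average over 20 draws. The HB100 counts themselves were not used there, so traits of those 3 libraries did not enter. The log2 fold changes correlated at 0.678 across genes, which are not independent replicates, and at 0.513 in the simulated groups; the covariance was 0.8754 against 0.08295. As 3 controls cannot be split into groups of 2, part of the excess may come from the shared HB100 libraries. The shared count was 769 without HB100 replicate 2, and 795 and 794 without TMS-IBA 980581 replicate 1 or 3. With the resistant lines averaged, 3037 genes (13.3%) differed from HB100, 1362 higher and 1675 lower, and 6534 at an unadjusted p under 0.05; the count was 1965 without HB100 replicate 2. On the TPM scale the share that was higher went from 44.8% to 56.3%. The chloroplast-encoded list passed alone (median -0.73, 6 of 58 lower, 0 adjusted over the list alone, 21 at an unadjusted p under 0.05, 16 by DESeq2, camera adjusted p = 0.00019, adjusted p = 0.95 with an estimated correlation and 0.46 without HB100 replicate 1). Among called shares, NLR genes stood at 30.5% against 13.2%, receptor-like genes at 23.8% against 13% and starch genes at 26.5% (exact adjusted p = 4e-08, 5.9e-12 and 0.032). Photosystem genes had 0 of 80 called by edgeR, 0% against 13.4% (exact adjusted p = 0.00023), with 5 at an unadjusted p under 0.05 and 3 by DESeq2.

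Whether the resistant lines differ from each other was asked by comparing them directly, which also tests whether their differences from HB100 are alike. The amidase gene LOC110612932 (38.9 ± 6.26 CPM in MKUC64-36-160) was at least 1130-fold higher in MKUC64-36-160 than in TMS-IBA 980581, and PERK15 and PERK14 (21.4 ± 3.08 and 19.4 ± 2.64 CPM) at least 605-fold and 550-fold. A PERK1 pseudogene (LOC110612734) and an EG45-like gene (LOC110600291) were at least 430-fold and 262-fold higher, with limma-voom at adjusted p of 0.065 and 0.13, and the second lost its call without TMS-IBA 980581 replicate 2 (0.052). Endochitinase 1 (LOC110612600) was at least 276-fold lower, the receptor kinase FERONIA gene LOC110615268 at least 211-fold, RLP15 LOC110612655 at least 195-fold and the P450 gene LOC110627654 at least 209-fold. A further 71AU50 gene (LOC110628019) fell by 5.07 ± 0.47 on the log2 scale, from 10.9 ± 2.44 to 0.324 ± 0.196 CPM. FERONIA and RLP15 differed from HB100 in opposite directions, higher in TMS-IBA 980581 by 3.64 ± 0.45 and 3.25 ± 0.42 and at least 16.4-fold and 19.8-fold lower in MKUC64-36-160.

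NLR and receptor-like genes were lower in MKUC64-36-160 than in TMS-IBA 980581 as groups with the preset correlation of camera; with an estimated one these lists and the abscisic acid list had an adjusted p of 0.91. Of 177 NLR genes 6 rose and 21 fell (8 and 32 adjusted over the list alone; median -0.21, camera adjusted p = 2.2e-05), and of 656 receptor-like genes 27 rose and 47 fell (34 and 71; median -0.14, adjusted p = 0.019). Their called shares were 15.3% and 11.3% against 3.96% and 3.83% of other genes (exact adjusted p = 5.4e-08 and 5.3e-14). NLR gene UNI (LOC110609192) fell from 13.2 ± 3.91 to 0.535 ± 0.318 CPM, LOC110608397 by 1.91 ± 0.22 and the RGA1-type LOC110607580, higher than HB100 in both lines, by 1.35 ± 0.16; RLP1 LOC110600226 fell by 3.43 ± 0.34. Abscisic acid genes were lower too, with 3 of 50 members lower and 0 higher (median -0.22, adjusted p = 0.019; 6 adjusted over the list alone). ABA 8'-hydroxylase 4 (LOC110624640) fell from 54.4 ± 7.69 to 24.4 ± 2.44 CPM and Lea5 (LOC110610555) by 1.08 ± 0.18, while Lea14-A (LOC110616077, adjusted p = 0.047) lost its call without any 1 of 8 libraries (0.056 to 0.16). At an unadjusted p under 0.05, 0 abscisic acid genes were higher, and DESeq2 called 0 of them higher. The receptor-like call ended without TMS-IBA 980581 replicate 1 (0.4) or MKUC64-36-160 replicate 3 (0.52).

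Ribosomal protein and photosynthesis genes were higher in MKUC64-36-160 than in TMS-IBA 980581 as groups with the preset correlation of camera, but single libraries overlapped. Mean log2 CPM of the ribosomal list was 4.94 in MKUC64-36-160 replicate 1 and 5.07 in TMS-IBA 980581 replicate 1. For photosystem genes it was 8.27 in MKUC64-36-160 replicate 2 and 8.47 in TMS-IBA 980581 replicate 3. For cytosolic ribosomal proteins the median was 0.38, with 245 of 256 members above 0 (camera adjusted p = 5e-15), and 8 rose and 1 fell (5 and 1 adjusted over the list alone). L3-2 (LOC110624418), ribosomal protein SA (LOC110600851) and S29-like LOC122723647 rose by 0.95 ± 0.19, 0.76 ± 0.16 and 0.59 ± 0.12, but on the TPM scale, where the median of all genes was -0.18, none of these calls held (adjusted p = 0.21, 0.38 and 0.45), nor without any 1 of 5 libraries (0.052 to 0.13). Photosystem genes had a median of 0.43 (77 of 80 above 0, adjusted p = 7.1e-07), chloroplast-encoded genes 0.46 (58 of 58, adjusted p = 0.0014) and chlorophyll synthesis genes 0.24 (21 of 26, adjusted p = 0.042). Heat shock proteins had a median of -0.32 (16 of 69 above 0, adjusted p = 0.0024). In these 4 lists edgeR called 0 members; 8, 0 and 4 members of the former were higher and 14 heat shock genes lower at an unadjusted p under 0.05, and DESeq2 called 1, 0, 2 and 0. Levels in TMS-IBA 980581 and MKUC64-36-160 were 441 ± 49.7 and 761 ± 69.8 CPM for the light-harvesting gene LOC110617228 (0.79 ± 0.26, adjusted p = 0.16) and 33.3 ± 6.76 and 57 ± 7.56 CPM for a protochlorophyllide reductase gene (LOC110610272, 0.78 ± 0.22, adjusted p = 0.098). The plastid genes rbcL, psbJ and psbB stood at 0.77, 0.72 and 0.64 (adjusted p = 0.42, 0.45 and 0.46), and heat stress factor A-6b (LOC110620422) at -1.17 (0.2). Mean rRNA shares were 16.6% and 20.5%. Without TMS-IBA 980581 replicate 1 the chloroplast-encoded and chlorophyll calls ended (0.2 and 0.2), as they did without MKUC64-36-160 replicate 3 (0.41 and 0.33), and the chlorophyll call also without TMS-IBA 980581 replicate 2 (0.27); with the rRNA covariate they were at 0.9 and 0.34. All 8 lists had an adjusted p of 0.91 with an estimated correlation, and fry's test of 1 direction called 0 lists, with 3 of 37 at an unadjusted p under 0.05.

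Between the resistant lines 923 genes (4.05%) differed, 443 higher and 480 lower in MKUC64-36-160, and 3704 at an unadjusted p under 0.05. All 923 lacked overlap between the libraries of the lines, as did 23.4% of all tested genes, against the 10% of chance. Of them 759 also differed from HB100 in a resistant line, and 23 genes differed from HB100 in opposite directions, among them the Nramp5 metal transporter gene LOC110616914, with 15.3, 1.7 and 64 CPM in HB100, TMS-IBA 980581 and MKUC64-36-160, and the SDE3 RNA helicase gene LOC110619208, with 19.7, 2.43 and 47.4 CPM; these 2 were chosen after their values were seen. The count was 444, 403 and 472 without TMS-IBA 980581 replicates 1, 2 and 3 and 586 without MKUC64-36-160 replicate 2. On the TPM scale the share that was higher went from 48% to 23.9%.

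Genes that differed from both other lines in the same direction numbered 434 in TMS-IBA 980581 (199 higher, 235 lower) and 348 in MKUC64-36-160 (144 and 204), beside the 1271 of HB100. Without TMS-IBA 980581 replicate 1, 2 or 3 they were 209, 202 and 224 in that line and 197, 173 and 202 in MKUC64-36-160. Against the mean of the others, 3037 genes differed in HB100, 1497 in TMS-IBA 980581 and 1236 in MKUC64-36-160. Genes at a mean of 5 CPM or more in the other lines and without a read in 1 line were few. HB100 had no read for 6, TMS-IBA 980581 for 8 and MKUC64-36-160 for 5. Whether these genes are missing from the line, too diverged to align or not expressed was not tested. The 8 of TMS-IBA 980581 included the 3 PERK genes, the amidase gene and a telomerase Cajal body protein 1-like gene (LOC110625209, at least 388-fold lower than in HB100). The 5 of MKUC64-36-160, listed after their values were seen, were endochitinase 1, the pseudogenes LOC110607916 and LOC122725267 and the uncharacterized genes LOC110626492 and LOC122725120.

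Called genes were not spread evenly over the 18 chromosomes. Chromosome 1 held a higher share in TMS-IBA 980581 against HB100 (14.2% of its tested genes against 10.9% elsewhere, Fisher's exact adjusted p = 0.00027) and between the resistant lines (5.84% against 3.91%, 0.0015). Chromosome 7 held a higher share in both resistant lines against HB100 (13.9% against 11.1%, 0.042, and 15.8% against 10.1%, 2.3e-06). Chromosome 10 was higher in TMS-IBA 980581 against HB100 (14% against 11%, 0.036) and between the resistant lines (6.31% against 3.97%, 0.004). Chromosome 18 was higher in MKUC64-36-160 (12.8% against 10.2%, 0.043). Lower shares were found on chromosome 15 in both (8.6% and 8.16%, 0.014 and 0.035), on 12 and 13 in MKUC64-36-160 (7.91% and 8.01%, 0.035 and 0.042) and on 3 between the resistant lines (2.43%, 0.004). At a log2 fold change of at least 1, chromosome 1 no longer stood out in TMS-IBA 980581 (7.85% against 7.04%, 0.28) or between the resistant lines (3.32% against 2.93%, 0.5), nor did 13 and 18 in MKUC64-36-160 (0.14 and 0.18). At that threshold chromosome 11 held a higher share (8.79% against 6.57%, 0.016) and chromosome 1 a lower one (5.33% against 6.82%, 0.04) in MKUC64-36-160 against HB100, and chromosomes 5 and 15 lower ones between the resistant lines (1.72% and 1.84%, 0.021 and 0.046). Fisher's test takes genes as independent, while neighbouring genes were often called together, so these p-values may be too small. With a filter of 5 CPM in 3 libraries, 1 chromosome stood out in TMS-IBA 980581 and 0 in MKUC64-36-160.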

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

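The tests against the rRNA share, without HB100 replicate 1, of mitochondrial transcripts, of strongly reduced receptor genes and of neighbouring receptor genes against other neighbours were chosen only after the results they bear on were seen; the comparison of the resistant lines and the share of neighbouring receptor genes called in opposite directions were not. Each value in the next 2 paragraphs drew attention because the effects of the resistant lines against HB100 differ, by the direct test of MKUC64-36-160 against TMS-IBA 980581. In that test 923 genes differed, and 23 genes were called against HB100 in opposite directions.

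The log2 difference, MKUC64-36-160 minus TMS-IBA 980581, was -1.23 for syntaxin-51-like LOC122722368, -1.22 for cell number regulator LOC110620072, -1.21 for NLR gene LOC110622556 and -1.25 for glucanase LOC110609347, which are higher than in HB100 in both lines. It was 1.37 and 2.24 for PAD4 genes LOC110627739 and LOC110628137, which are lower in both. For genes of the receptor-like list it was -2.45 (RLP1 LOC122721772), -2.68 (CRK10 LOC110604445) and -2.79 (RLP15 LOC110608438), for CBP60A (LOC110630838) -0.59 and for ribosomal protein L3-2 (LOC110624418) 0.95, whose call ended without any 1 of 5 libraries (adjusted p 0.052 to 0.1). Where a line had no read the fold between the lines is a lower bound. It was at least 209 for P450 gene LOC110627654 and 276 for endochitinase 1 LOC110612600, without a read in MKUC64-36-160. For genes without a read in TMS-IBA 980581 it was at least 1130 for the amidase gene LOC110612932 and 605 for PERK15 LOC110608280. It was at least 550 for PERK14 LOC110607770 and 58.9 for LOC110616843, also without a read there.

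Gene lists differed between the resistant lines by medians of 0.38 for cytosolic ribosomal proteins, 0.43 for photosystems, 0.46 for chloroplast-encoded genes and 0.24 for chlorophyll synthesis, and of -0.32 for heat shock proteins, -0.22 for abscisic acid genes, -0.21 for NLR receptors and -0.14 for receptor-like genes. All 8 passed camera with its preset correlation and none with an estimated one (adjusted p = 0.91). The chloroplast-encoded, chlorophyll and receptor-like lists no longer passed without TMS-IBA 980581 replicate 1 or MKUC64-36-160 replicate 3 (camera adjusted p 0.2 to 0.52), nor did chlorophyll without TMS-IBA 980581 replicate 2 (0.27).

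Chloroplast-encoded transcripts were lower in the resistant lines than in HB100, with medians of -0.97 and -0.46 (SD between members 0.41 and 0.4). Within lines their level moved with the log2 rRNA share of the library (r = 0.86 over 9 libraries, exact permutation p = 0.0093, one-sided, 216 permutations; rho = 0.87, exact p = 0.014, two-sided), and r was 0.98 without MKUC64-36-160 replicates 2 and 3, which deviate most from their line in share, 0.93 without HB100 replicate 1, and 0.88 without HB100 replicate 1 and MKUC64-36-160 replicate 3. Carry-over of RNA without poly(A) is a candidate explanation, since transcripts of 31 mitochondrial genes were lower too (median -1.31 in TMS-IBA 980581, where random lists gave -0.19 to 0.18). With the rRNA share as a covariate the chloroplast median came to 0.03. But that share was mostly chloroplast rRNA (28.1 of 30.8% in HB100 replicate 1, 13.2 of 14.5% in TMS-IBA 980581 replicate 1). A chloroplast difference of any cause would move with it, so neither r nor the covariate fit tells carry-over from such a difference. HB100 replicate 1 carried much of the difference: without it the median was -0.37 in TMS-IBA 980581 and 0.14 in MKUC64-36-160. A difference between the lines in organelle transcripts themselves stays open, because the rRNA share also differs between lines.

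NLR and receptor-like genes were over-represented among the genes that differ between MKUC64-36-160 and HB100. Reads shared between neighbouring copies stay open: 8 of 31 adjacent called pairs went opposite ways (share 0.258, exact 95% interval 0.119 to 0.446), under the bound of 0.5 set beforehand, but so did 144 of 402 other adjacent called pairs (odds ratio 0.624, 95% interval 0.235 to 1.49, exact p = 0.33), and reads counted on each copy would move copies the same way. Alleles missing from 1 line or too diverged to align are a candidate explanation that stays open too. The lower line was at most 1/8 of the higher one in 46 of 180 called members (25.6%) and 320 of 1956 other called protein-coding genes (16.4%), but within 7 bins of expression the odds ratio was 1.08 (95% interval 0.707 to 1.64). A difference in the regulation of these genes between the lines was not tested, as reads were not analysed here.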

How the results depend on the processing

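The fits with the rRNA share as a covariate, without organelle and rRNA genes, and without HB100 replicate 1 and MKUC64-36-160 replicate 3 together were chosen only after seeing the data. In what follows, values are for TMS-IBA 980581, MKUC64-36-160, the direct comparison of the resistant lines, their mean, the shared genes, and the genes that set TMS-IBA 980581 and MKUC64-36-160 apart, in that order unless said otherwise. Median-of-ratios factors and no low-count filter, limma-voom, limma on TPM, and leaving out organelle and rRNA genes moved no count of calls by over 1.5 times. The genes called changed more than the counts. In the 3 comparisons of lines median-of-ratios factors kept 99.2%, 98.8% and 99% of the main calls, but limma on log2 of TPM + 1 kept 64.7%, 58.5% and 63.4%. The covariate kept 44.5%, 74.5% and 79.6%. Fewer genes tested (5 CPM in 3 libraries) gave 1597, 1487, 486, 1939, 774, 220 and 216. DESeq2 gave 3577 for MKUC64-36-160, 1729 between the resistant lines, and 764 and 635 apart. Only the libraries of the lines compared gave 1458 for MKUC64-36-160. For the mean that fit was not run, because the mean needs the libraries of all lines. A log2 fold change of at least 1 left 1647, 1538 and, for the mean, 1731. A test against a fold of 1.5 left 960, 918, 377, 1041, 470, 172 and 133, and a model of 2 classes 2017. The covariate gave 1435 for TMS-IBA 980581, and leaving out the libraries of highest rRNA share 1398 for MKUC64-36-160. Apart from the settings with fewer genes or libraries or a stricter test, the cause was not tested.

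A block by the replicate number of the title gave 1555, 1276, 406, 1906, 710, 199 and 152 calls, and 5 lists for TMS-IBA 980581 and 6 for the mean. A block by the number of the description gave 5 lists for the mean and moved no other count by over 1.5 times. Between HB100 and MKUC64-36-160 the description numbers met the bound of 0.1 taken as pairing (correlations 0.198, 0.24 and 0.168), and that block gave 2512 calls and 7 lists there. Libraries that shared neither number also reached 0.228, and the labels name no pairing, so pairing is not established. Elsewhere not every same-numbered pair correlated, and the title numbers averaged 0.016, so calls lost under the title block are not described as weaker effects.

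Leaving out 1 library at a time gave 1414 to 2743, 1448 to 1994, 403 to 1056, 1965 to 2835, 769 to 1013, 202 to 441 and 173 to 330 calls. Lists past the threshold then ranged from 0 to 3 for TMS-IBA 980581, 3 to 6 for MKUC64-36-160, 5 to 9 between the resistant lines and 1 to 4 for the mean.

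Counts of lists depended on the assumed correlation: camera with an estimated correlation passed 0, 0, 0 and 0 lists in the 4 comparisons, 0 of 37 also at an unadjusted p under 0.05, and fry's test of 1 direction passed 2, 0, 0 and 4 (4, 6, 3 and 7 unadjusted), while its test of change in either direction, which compares no list with other genes, passed 29, 31, 22 and 31 of 37. The 2 were flower organs (higher) and senescence (lower), to which the mean added salicylic acid and starch genes. With the covariate 6 lists passed for TMS-IBA 980581 and 7 for the mean, and the chloroplast-encoded list changed direction (adjusted p = 0.84, 0.44 and 0.65 for TMS-IBA 980581, MKUC64-36-160 and the mean), as it did for MKUC64-36-160 without HB100 replicate 1 (0.66). Leaving out 1 library at a time, its adjusted p in MKUC64-36-160 ranged from that value down to 0.0002, without MKUC64-36-160 replicate 3. Without the libraries of highest rRNA share 2 lists passed for MKUC64-36-160 and 0 for the mean. Chromosomes with an uneven share of calls were 1 for TMS-IBA 980581, 0 for MKUC64-36-160 and 0 for the mean with the filter of 5 CPM, and 4 for the mean at a log2 fold change of at least 1. Genes counted as without reads in HB100 numbered 28 when up to 1 CPM was allowed there. When the others needed 1 CPM they numbered 22, with 20 for TMS-IBA 980581 and 15 for MKUC64-36-160.

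Over the fits in which named genes were followed, 2276 values of single genes kept their side of the threshold. In 114 the call was lost and in 31 one was gained. Of genes called in the main fit 0 changed direction, while the direction of genes without a call was not followed. Lists were followed only where they had passed, so no list could gain a pass. Of their values 178 kept the pass, 74 lost it and 4 changed direction. Fits of only the lines compared, without organelle and rRNA genes, of 2 classes, or with stricter fold thresholds were not tallied. At these depths a single library without a count for a gene allows up to 0.15 CPM. Simulated 2-fold changes in TMS-IBA 980581 were called in 34% of genes, with 200 genes changed. The real comparison with HB100 called 2564 genes, and the adjustment of p-values is less strict when more genes differ. The 34% is therefore not the sensitivity of the real comparisons. Counts of called genes may leave out smaller differences, but how many was not tested.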

Other observations

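The tests of neighbouring genes of different product names, of runs of called genes, and the genes named in the next 3 paragraphs were chosen only after values were seen; the splits of the libraries were not.

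Single genes of carbohydrate and phosphate metabolism differed from HB100 in both resistant lines. Of 68 starch and sucrose genes 6 rose and 5 fell in both (16.2%, against 5.54% of other genes); the called share stood out in TMS-IBA 980581 (27.9% against 11.2%, exact adjusted p = 0.0012) but not in MKUC64-36-160 (16.2% against 10.3%, 0.38). Beta-amylase 1 (LOC110610007), an enzyme of starch breakdown, fell from 19 ± 0.697 CPM in HB100 (SD, n = 3) to 1.96 ± 0.291 in TMS-IBA 980581 and 2.97 ± 0.0873 in MKUC64-36-160, and beta-amylase 2 (LOC110614410) from 19.1 ± 2.24 to 4.49 ± 0.305 and 4.64 ± 0.806. A SWEETIE-like gene (LOC122724082) rose from 1.29 ± 0.0989 to 16.3 ± 1.22 and 26.2 ± 1.44 CPM. Of 100 genes of the phosphate and nitrate list 4 rose and 6 fell in both (10% against 5.55%), and the called share was 14% against 11.2% in TMS-IBA 980581 (exact adjusted p = 0.61) and 20% against 10.3% in MKUC64-36-160 (0.026). The phosphate transporter gene LOC110610840 fell from 11.6 ± 2.62 to 1.25 ± 0.342 and 0.572 ± 0.321 CPM, and purple acid phosphatase 3 (LOC110601105) rose from 7.1 ± 1.07 to 41.6 ± 16.5 and 54.7 ± 13 CPM. These 5 calls held in each of 22 other fits in both lines (adjusted p in edgeR at most 0.00085). Further genes, not described here, were followed through the same fits, and most of them lost a call in at least 1. LOC110613309 lost its call in 13 of 22 fits in MKUC64-36-160, and LOC110600247 in 12 of 22 in TMS-IBA 980581. The genes named here and in the next paragraph are mostly those whose calls held. How often calls of other genes hold cannot be read from them.

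Single genes of the leaf surface, ethylene and secondary metabolism were called as well, although the called shares of the cuticle, ethylene, lignin and terpenoid lists did not stand out in TMS-IBA 980581 (11.4%, 11.9%, 15.8% and 24.2% against 11.2%, exact adjusted p = 1, 0.96, 0.61 and 0.12), nor those of the last 3 in MKUC64-36-160 (15.8%, 12.3% and 18.2% against 10.3%, 0.33, 0.95 and 0.45). Of other genes about 5.56% were called the same way in both lines. In the cuticle and wax list 4 of 44 rose and 1 fell in both resistant lines (11.4%), and lipid-transfer protein 1 (LOC110623629) rose from 0.638 ± 0.158 to 10.4 ± 3.97 and 12.4 ± 6.17 CPM. In the ethylene list 8 of 101 rose and 1 fell in both (8.91%); ACC oxidase (LOC110602827), which makes ethylene, rose from 6.03 ± 4.72 CPM to 34.6 ± 16.6 in TMS-IBA 980581 and 157 ± 82.1 in MKUC64-36-160, the former without a call in 8 of 22 other fits, among them those without HB100 replicate 1 or 3 or TMS-IBA 980581 replicate 1 or 2 (adjusted p in edgeR 0.09, 0.089, 0.091 and 0.055). Lignin genes fell where they changed in both, 4 of 57 (7.02%), among them caffeic acid 3-O-methyltransferase (LOC110627924), from 3.79 ± 0.532 to 1.34 ± 0.487 and 0.668 ± 0.0536 CPM, although its call in TMS-IBA 980581 ended in 3 of 21 other fits, among them those without replicate 1 or 2 of that line (adjusted p in edgeR 0.051 each). Terpenoid genes had 5 of 33 higher in both and 1 lower (18.2%), with terpene synthase 8 (LOC110608594) at 1.61 ± 0.55, 16.6 ± 2.75 and 15.1 ± 5.3 CPM. A chloroplast small heat shock protein (LOC110629593) fell from 90.1 ± 7.63 to 35.9 ± 7.4 and 39.2 ± 3.99 CPM, and a Cu-Zn superoxide dismutase (LOC110621687) rose from 30.3 ± 5.6 to 70.2 ± 7.46 and 76.5 ± 18.8 CPM. The calls of the lipid-transfer, terpene synthase, heat shock and dismutase genes held in each of 22 other fits in both lines (adjusted p in edgeR at most 0.0051).

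The other lists had these members called in TMS-IBA 980581 and in MKUC64-36-160 against HB100, as edgeR called them over all genes. Higher and lower were 5 and 9, then 4 and 4, of 108 auxin genes, 10 and 2, then 11 and 5, of the ethylene list, and 3 and 2, then 3 and 1, of 56 jasmonate genes. RNA silencing had 2 and 3, then 2 and 4, of 40, RNA-directed DNA methylation 3 and 0, then 1 and 1, of 27, DNA replication 3 and 3, then 1 and 1, of 35, and pathogenesis-related genes 4 and 2, then 3 and 4, of 88. For glutathione S-transferases the calls were 3 and 4, then 0 and 6, of 44, for reactive oxygen enzymes 4 and 3, then 4 and 0, of 47, for class III peroxidases 1 and 0, then 2 and 2, of 25, and for heat shock proteins 5 and 5, then 2 and 5, of 69. Lignin genes had 1 and 8, then 1 and 6, of 57, with a median of 0.01 and a mean of 0.16 in TMS-IBA 980581 where camera's direction was down. Flavonoid genes had 1 and 3, then 0 and 4, of 50, terpenoid genes 5 and 3, then 5 and 1, of 33, cyanogenic glucoside genes 2 and 1, then 3 and 1, of 39, cuticle genes 4 and 1, then 8 and 3, of 44, and phosphate genes 6 and 8, then 9 and 11, of 100. Called cuticle and phosphate genes made up 25% and 20% of their lists in MKUC64-36-160, against 10.3% of other genes (exact adjusted p = 0.026 for both).

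Cell cycle genes had 1 and 0, then 4 and 0, of 84 called, proteasome genes 2 and 3, then 2 and 2, of 65, and senescence genes 0 and 2, then 0 and 1, of 14. Clock genes had 0 and 0, then 2 and 0, of 29 (in TMS-IBA 980581 2 at an unadjusted p under 0.05 and 0 by DESeq2), and autophagy genes 0 of 29 in both lines (4 and 6 at an unadjusted p under 0.05, and 0 and 1 by DESeq2). Markers of other cell types had these calls: guard cells 2 and 2, then 0 and 1, of 17, phloem 4 and 0, then 1 and 1, of 17, xylem 0 and 0, then 1 and 0, of 5, and flower organs 1 and 0, then 0 and 0, of 12. Where these had no call, unadjusted p was under 0.05 for 0 xylem genes in TMS-IBA 980581 and 2 flower genes in MKUC64-36-160, and DESeq2 called 0 of either. Median log2 fold changes in TMS-IBA 980581 and MKUC64-36-160 were 0.48 and 0.5 for guard cells, 0.66 and 0.42 for phloem and 1.19 and 1.94 for xylem, whose 5 members were all above 0 in both, without a pass in camera (adjusted p 0.31 for each in the former and 0.24, 0.75 and 0.087 in the latter). Called shares of guard cell and phloem markers in TMS-IBA 980581 were 23.5% each against 11.2% (exact adjusted p = 0.33). The 5 genes of translation initiation factors 4E and 4G had no call in either line, with 0 and 1 at an unadjusted p under 0.05 and 0 by DESeq2. None of the lists in these 2 paragraphs passed camera against HB100. Medians of the auxin, cell cycle, flavonoid, phosphate, glutathione S-transferase, reactive oxygen, ethylene, cuticle, senescence and autophagy lists in TMS-IBA 980581, all between -0.26 and -0.02, turned positive on the TPM scale, where the median of all genes was 0.17.

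Called genes lay in runs along the chromosomes. In TMS-IBA 980581 against HB100, 324 pairs of adjacent tested genes were called in the same direction, where 1000 permutations gave 122 to 166 (95% of them), and 281 and 101 pairs in the other comparisons of lines against 103 to 144 and 12 to 28. Neighbours of the same product name do not account for all of it, as 261 of the pairs had different product names (117 to 160 permuted). Copies may still be among these, since uncharacterized genes each have a name of their own, so copies are not excluded. The runs may come from stretches of the genome that differ between the lines, which would give an excess of such pairs. Copies of a gene, reads that run through into a neighbour or overlapping genes would give an excess too, and no test separated these. Genotypes were not analysed here.

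Splits of the libraries into other groups show how far chance can be excluded. For the 3 pairwise comparisons only 10 splits exist, too few for a share under 0.05: the real split gave 2564, 2357 and 923 genes and was 1 of 10 as large each time, with 0 genes at most in the others. List counts of the real splits, 1, 6 and 8, were reached by 10, 8 and 7 of 10 splits, and the highest of the others were 9, 15 and 13. For HB100 and MKUC64-36-160, whose description numbers met the bound taken as pairing, the other splits that part every same-numbered pair gave 5, 7 and 15 lists. Those that keep such a pair together gave 4 to 12. For the mean of the resistant lines, 1 of 100 splits into 3 groups of 3 gave as many as the real 3037 genes (highest other 1977, a split that kept HB100 whole). A chance split of the libraries is thus excluded there at a share under 0.05, in the sense that the HB100 libraries hold together. The same holds for the 1271 shared genes (1 of 100, highest other 815) and the 2-class model (2017, 1 of 84, highest other 441). Drawn splits that mixed the resistant lines but kept HB100 as the reference still gave 1977 and 1795 genes, and 815 and 735 shared genes. The shares thus do not bear on how the resistant lines are grouped. The 434 genes that set TMS-IBA 980581 apart were reached by 4 of 100 splits, and the 348 of MKUC64-36-160 by 1 of 100 (highest other 82). But 6 of the 100 splits kept HB100 whole, and 4 of these 6, the real one among them, reached 434. Drawn splits with HB100 in the place of TMS-IBA 980581 gave 725 to 815 genes. No drawn split put HB100 in the place of MKUC64-36-160, so the share for the 348 rests on which splits were drawn. For these counts chance is therefore not called excluded. The list count of the mean, 1, was reached by all 100 splits, with a highest other of 14, so for it chance is not excluded.

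HB100 had the higher level of AGO2 and both PAD4 genes. Whether this is a response to the CMV treatment or a trait of the line was not tested, because no untreated leaf was compared. Virus reads were not analysed here, so which leaves were infected is not known.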
